A study of Homo sapiens with 20 samples.

How the data were processed

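The samples were grouped by their titles, which name the treatment and the islet source, into 4 groups of 5 libraries from 5 sources. The submitters' processing notes name cutadapt, FastQC, STAR, HTSeq and the genome build hg19, and their roles and versions are not given in the sources used here. A table of raw counts and a table of normalized counts were deposited by the authors for the whole series. Each table has 20 columns of values under a sample code, and 20 of 20 codes in each matched no label of any sample, so neither table was used. The column headers were compared with each sample's accession, title, description, source name and characteristics, first for equality and then for a header contained in a label with case and punctuation ignored. The second rule was chosen after the files were seen. Tests of differential expression, of gene lists and of a DFMO by cytokine interaction had been laid down before the data were examined. So had a test of whether DFMO moves genes against the cytokine effect. None of these tests was run.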

Results

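RNA sequencing was carried out on human pancreatic islets from 5 organ sources, giving 20 libraries in 4 groups of 5. Islets of each source were left unstimulated, treated with DFMO, treated with the proinflammatory cytokines IL-1β and IFN-γ, or treated with DFMO and both cytokines. Each treatment lasted 24 h, and no time is given for the unstimulated islets. DFMO (difluoromethylornithine) is an irreversible inhibitor of ornithine decarboxylase, the enzyme that converts ornithine to putrescine in polyamine synthesis. IL-1β and IFN-γ are used on islets in culture as a model of the inflammation of autoimmune diabetes. The design compares cytokine-treated with unstimulated islets and DFMO-treated with unstimulated islets. Islets given DFMO and cytokines are compared with islets given cytokines alone and with islets given DFMO alone. It also allows a test of whether the response to DFMO differed with and without cytokines.

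None of these comparisons is reported, and no expression value is given. The tables of raw and of normalized counts each hold 20 columns of values, headed by a sample code. In each table, 0 of the 20 column codes equalled a label of a sample, and the codes name neither a treatment nor an islet source. The columns were therefore assigned to no library and no group. Column order was not used in place of a label, since no label ties it to the samples. Expression values were not used either. A treatment assigned from the expression of cytokine-responsive genes would have fixed in advance the result of comparing islets with and without cytokines.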

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

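The number of columns matched to a sample label was 0 in both tables when the header had to equal a label, and 0 when it had only to lie inside one with case and punctuation ignored. The second rule was chosen after the files were seen. No paired analysis was possible because the columns carry neither a group nor a source number. Other choices of normalization, filter, test and left-out library were not run for the same reason.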
